A study of Mus musculus with 12 samples.

How the data were processed

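RNA from mouse hippocampus was measured in 12 libraries, 3 in each of 4 groups taken from the labels: WT, 5xFAD, Ulk1OV and 5xFAD;Ulk1OV. Libraries were made with a NEBNext Ultra RNA kit, per the labels. The deposited table holds read counts per gene for every library, not normalized. FastQC, Trim Galore, HISAT2, SAMtools, featureCounts and DESeq2 and the mouse build mm10 are named in the submitters' processing notes, without versions. Their settings, the annotation and whether counting used strand are not given in the sources used here, so counts of paralogs, pseudogenes and overlapping genes are uncertain. The table lists 54427 genes, 22784 of them at 0 in every library, and 24 symbols had turned into calendar dates. Totals per library ran from 16149992 to 18547132 counts. Molecular identifiers were not used here, so floors cover counting error only.

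From these counts edgeR 4.0.16 in R 4.3.3 kept 17227 genes by its default filter on low counts and scaled libraries by TMM. Its quasi-likelihood test was fitted to all 12 libraries with 1 mean per group, so the 4 groups share the estimate of the spread. Contrasts gave 4 comparisons (5xFAD against WT, 5xFAD;Ulk1OV against 5xFAD, Ulk1OV against WT, 5xFAD;Ulk1OV against Ulk1OV) and their interaction. A gene was called at an adjusted p under 0.05 after Benjamini-Hochberg adjustment. Standard errors are the log2 fold change divided by the square root of F. Levels are given as CPM, mean ± SD over 3 libraries. An exact permutation test of 3 against 3 cannot go below a two-sided p of 0.1, so single genes were tested with the model fitted across genes. Of 41 gene lists written before the data were examined, 40 were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with 5 to 43 members tested, and again with a correlation estimated per list, under which camera called 0 lists in each comparison. The sex list served only to compare libraries, which were alike in it. Each list's calls are also given adjusted over the list alone.

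Genes were named by a rule fixed beforehand. Ulk1, App, Thy1 and Prnp were always named. Some genes that the rule names are not reported here. In each comparison of groups, up to 8 genes per direction with the largest log2 fold change were named among those called, with non-overlapping replicates and a mean of at least 1 CPM; non-overlap arises by chance in 10% of genes at 3 against 3. The interaction named 5 per direction without the overlap condition. Where fewer than 3 genes passed, the 3 smallest p-values in each direction were named. Each list named up to 4 members with the smallest p. Lamr1-ps1, and Cst7 outside the rule, were named after their values were seen.

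Positions come from GENCODE M21 on GRCm38, the build called mm10, and 17111 of the tested genes (99.3%) had a transcript there for GC content and length. The edgeR tests and camera were tried on simulated counts with changed genes, while DESeq2 and the correction for GC content and length were not. For 5xFAD against WT, edgeR recovered 35.8% of genes changed 1.5-fold, 79.1% changed 2-fold and 92.4% changed 4-fold among 16963 genes, with 4.2% false calls. For the interaction it recovered 9%, 61.2% and 71.2% among 16968 genes, with 9.6% false calls.

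The alternatives were DESeq2 1.42.0, DESeq2's size factors, no filter on low counts, a replicate block, only the 6 libraries of a comparison, an estimated correlation for the lists, and each library left out in turn. A correction of each library's trend over GC content and transcript length (loess, span 0.4) was added after the data were seen, as were the values of 5xFAD against WT and Ulk1OV against WT without the library labelled 5xFAD;Ulk1OV replicate 3, and those of single genes with 6 libraries or 1 left out. A planned share of genes called in 5xFAD against WT was undefined, because edgeR called 0 genes there (2139 at an unadjusted p under 0.05, 136 by DESeq2), and a covariance over all genes took its place.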

Results

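RNA from mouse hippocampus was sequenced in 12 libraries from 4 groups of 3: wild type (WT), 5xFAD, Ulk1OV, and mice carrying both labels (5xFAD;Ulk1OV). 5xFAD is a transgenic mouse line that expresses mutant human APP in neurons and develops amyloid plaques. The labels describe Ulk1OV as overexpression of ULK1, the protein kinase that starts autophagy. The values were read counts per gene. In WT replicates 1, 2 and 3 the totals were 16913424, 18169767 and 17265625 counts, in 5xFAD 18411165, 17907104 and 18055187, in Ulk1OV 16149992, 17652128 and 18547132, and in 5xFAD;Ulk1OV 17598269, 18291136 and 17837398. Of 54427 genes listed, 17227 had enough counts to be tested. Mitochondrially encoded genes took 4.035% to 8.758% of the counts. Each of the 12 libraries had 0 to 3 Xist counts and 2071 to 2692 Ddx3y counts, the pattern of male tissue. Replicates of a group differed by more than sampling noise, with a chi-square per degree of freedom of 7.28 to 30.49 between pairs. The labels do not say that the replicates came from separate animals, so the p-values measure the spread between these libraries, which may be technical.

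The gene behind the Ulk1OV label was measured first. Ulk1 (GRCm38 chromosome 5, 110784488 to 110810097) averaged 77.8 ± 3.86 CPM in WT, 73.2 ± 11.7 in 5xFAD, 91.4 ± 9.29 in Ulk1OV and 93.6 ± 7.41 in 5xFAD;Ulk1OV (SD, n = 3 each). The 6 libraries with the Ulk1OV label lay between 84.6 and 102 CPM and the other 6 between 63.5 and 86.3, a 1.23-fold difference (log2 0.30, exact two-sided permutation test over 924 splits, p = 0.00649). In the separate comparisons Ulk1 did not pass the test: the log2 fold change was 0.23 ± 0.11 (SE) for Ulk1OV against WT (edgeR adjusted p = 0.229) and 0.35 ± 0.11 for 5xFAD;Ulk1OV against 5xFAD (edgeR adjusted p = 0.144). Reads of a transgene built from human ULK1 or from a coding sequence alone would be counted only where they align to the mouse gene, and the construct is not given in the sources used here.

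App, Prnp and Thy1, mouse genes that reads of a transgene might reach, were measured next, with the pseudogene Lamr1-ps1. App, the amyloid precursor gene (chromosome 16, 84949685 to 85173766), averaged 1415 ± 53.3 CPM in WT, 2526 ± 164 in 5xFAD, 1371 ± 126 in Ulk1OV and 2033 ± 655 in 5xFAD;Ulk1OV. Prnp, which encodes the prion protein (chromosome 2, 131909928 to 131938429), averaged 1025 ± 112, 2343 ± 186, 979.7 ± 32.4 and 1741 ± 685 CPM in the same order. Thy1, a neuronal surface glycoprotein gene (chromosome 9, 44043384 to 44048579), averaged 594.7 ± 43.5, 567.1 ± 52.4, 605.5 ± 22.4 and 579.3 ± 36.5 CPM. Lamr1-ps1, a processed pseudogene 4.97 kb upstream of Prnp (chromosome 2, 131904086 to 131904959), had 208 to 304 counts in the 5xFAD libraries and 0 in each WT and Ulk1OV library. Its mean in 5xFAD was at least 72.7-fold above the floor of 3 counts per library. Lamr1-ps1 resembles the ribosomal protein gene Rpsa, so its reads are uncertain, and it was chosen after its values were seen.

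The library labelled 5xFAD;Ulk1OV replicate 3 went against its label in these genes. It had 1310 CPM of App, where the other 5 libraries with a 5xFAD label had 2201 to 2667 and the 6 without had 1240 to 1493. It had 954 CPM of Prnp, against 2067 to 2510 and 900 to 1119. It had 0 counts of Lamr1-ps1, against 184 to 304 and 0. It also had 0.779 CPM of Cst7, a microglial gene, against 4.36 to 7.41 and at most 0.531. The number of genes called in each comparison that uses it is also given without it.

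**Figure D1:**
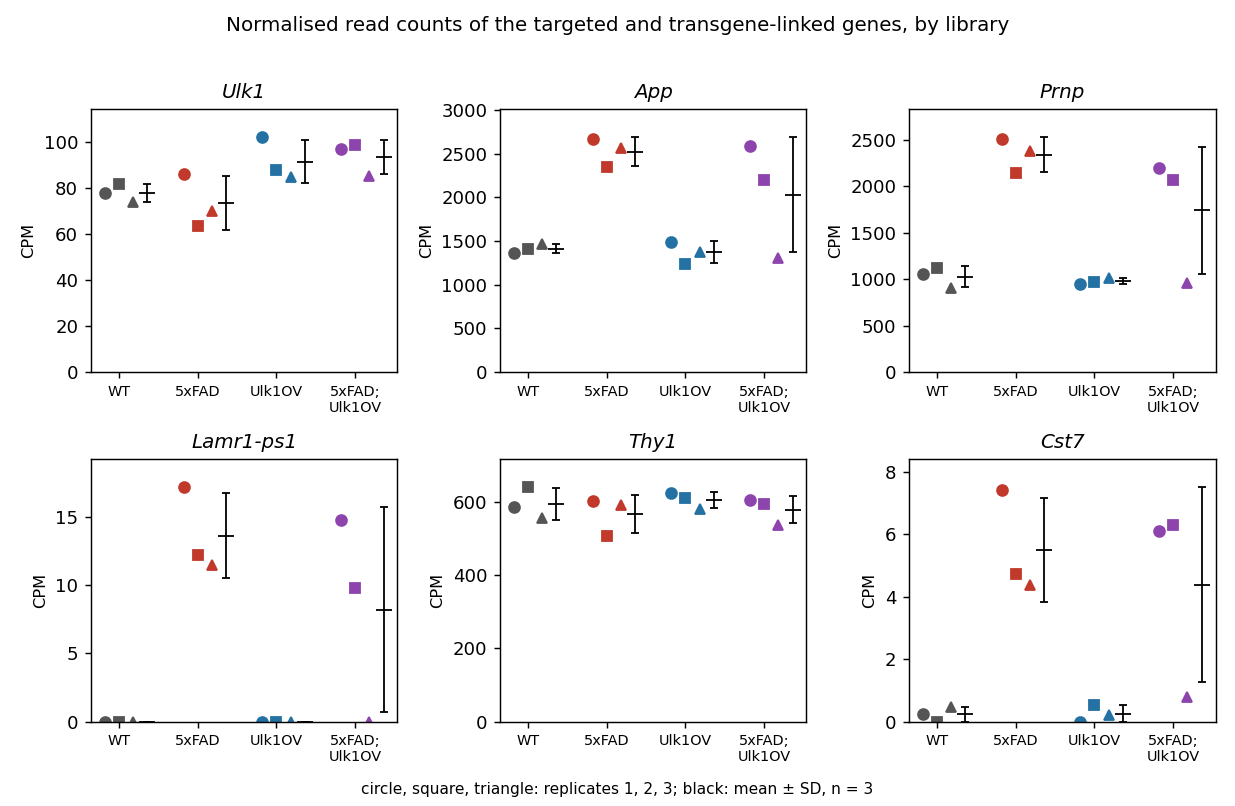
Normalised read counts (CPM) in each of the 12 libraries (circle, square and triangle for replicates 1, 2 and 3, by group, with mean ± SD in black, n = 3) for Ulk1, App, Prnp, Lamr1-ps1, Thy1 and Cst7. The library labelled 5xFAD;Ulk1OV replicate 3 has 1310 CPM of App and 954 CPM of Prnp and sits with the libraries without the 5xFAD label, while the other 5 libraries with that label have at least 2201 and 2067 CPM.

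The comparison of 5xFAD with WT asked what differs with the 5xFAD genotype when Ulk1 is not overexpressed. Cst7, a cysteine protease inhibitor, averaged 5.49 ± 1.67 CPM against 0.23 ± 0.227 in WT (SD, n = 3), Clec7a, a pattern recognition receptor, 3.48 ± 0.528 against 0.782 ± 0.355, and Ccl6, a chemokine, 6.64 ± 0.749 against 2.87 ± 0.178. The log2 fold changes were 4.55 ± 0.88 (SE), 2.15 ± 0.41 and 1.21 ± 0.23. Prnp differed by 1.19 ± 0.23 and App by 0.84 ± 0.18. Ndufa2 and Ndufa1, subunits of respiratory complex I, differed by -0.81 ± 0.14 and -0.73 ± 0.13, Myl6, a myosin light chain, by -0.57 ± 0.10 and Ddrgk1, a ufmylation factor of the endoplasmic reticulum, by -0.55 ± 0.09. Utp15, which works in ribosome assembly, differed by 0.48 ± 0.09. None of these genes passed the test: edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 0 of 17227 genes, with a lowest adjusted p of 0.111, while 2139 genes had an unadjusted p under 0.05 and DESeq2 called 136.

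Of 40 gene lists fixed before the data were examined, camera called 10 in 5xFAD against WT, 3 up and 7 down. Of 28 disease-associated microglia genes, 20 had log2 fold changes above 0 and 4 rose adjusted over the list alone (camera adjusted p = 5.24e-05, or adjusted p = 0.659 with an estimated correlation). Of 38 nuclear-encoded respiratory chain genes, 10 fell adjusted over the list alone (camera adjusted p = 2.22e-09, or 0.659 as adjusted p with an estimated correlation). Activity-dependent genes, which neurons switch on after firing, also shifted down, with 8 of 24 falling adjusted over the list alone (camera adjusted p = 1.07e-05, or 0.659 as adjusted p with an estimated correlation); Btg2 and Dusp1 had log2 fold changes of -0.95 ± 0.25 and -0.77 ± 0.22. Dentate gyrus markers shifted up, with 2 of 12 rising adjusted over the list alone, among them Pter at 0.47 ± 0.12 (camera adjusted p = 0.000156, or 0.659 as adjusted p with an estimated correlation, and 0.0568 by camera without WT replicate 2). Cholesterol synthesis genes shifted up with 0 of 20 members passing either way (camera adjusted p = 0.0491, or adjusted p = 0.804 with an estimated correlation). The cholesterol call ended without 5xFAD replicate 1 (0.143), WT replicate 1 (0.119) or WT replicate 3 (0.213).

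Several lists for cells of the vessels and the brain's coverings shifted down in 5xFAD. The lists of mural cells and of perivascular macrophages and leukocytes were not called (camera adjusted p = 0.135 each). Without 5xFAD replicate 2 both were called down (camera adjusted p = 0.0196 and 0.0162). The macrophage and leukocyte list was also called down without WT replicate 3 (camera adjusted p = 0.00245), without the filter on low counts (0.0198) and with the correction for GC content and length (0.0241). Meningeal and perivascular fibroblast markers fell adjusted over the list alone in 7 of 14 (camera adjusted p = 1.62e-08, or adjusted p = 0.659 with an estimated correlation), with Igfbp2 at -1.22 ± 0.28 and Col1a2, a fibrillar collagen chain, at -1.19 ± 0.39. Endothelial markers fell adjusted over the list alone in 4 of 16, with the tight junction gene Cldn5 at -1.15 ± 0.33 (camera adjusted p = 6.54e-07, or adjusted p = 0.659 with an estimated correlation). Antigen presentation genes fell in 1 of 18 adjusted over the list alone (camera adjusted p = 3.92e-05, or adjusted p = 0.659 with an estimated correlation, and 0.0582 by camera without 5xFAD replicate 1). Choroid plexus markers had a median log2 fold change of -2.66 over 16 genes (camera adjusted p = 0.000156, or adjusted p = 0.804 with an estimated correlation). That call ended without WT replicate 3 (camera adjusted p = 0.91) or 5xFAD replicate 1 (0.0884). Ttr, the most abundant choroid plexus transcript, stood at 5949 CPM in WT replicate 3 against 25 and 64.6 in the other WT libraries. Blood genes had a median of -0.50 over 5 genes (camera adjusted p = 0.0425, or adjusted p = 0.804 with an estimated correlation). The blood call ended without 5xFAD replicate 1 (0.143), 5xFAD replicate 3 (0.323) or WT replicate 1 (0.482).

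Without 5xFAD replicate 1 the count of genes in 5xFAD against WT went from 0 to 39. Without the library labelled 5xFAD;Ulk1OV replicate 3, which enters only through the shared estimate of the spread, it went to 3: Prnp (1.18 ± 0.10, edgeR adjusted p = 0.000286), App (0.82 ± 0.10, edgeR adjusted p = 0.0102) and Lamr1-ps1.

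The comparison of 5xFAD;Ulk1OV with 5xFAD asked what Ulk1 overexpression changes on the 5xFAD background. By edgeR's test 8 genes rose and 0 fell, but given the possible batch Ulk1 overexpression is not shown to be the source. Ndufa2 and Ndufa1 rose by a log2 fold change of 0.94 ± 0.14 and 0.87 ± 0.13, from 36.1 ± 2.16 to 69.3 ± 8.47 CPM and from 30.2 ± 2.64 to 55.3 ± 6.33 (SD, n = 3). Tceal5 and Tceal3, which encode proteins resembling the elongation factor TFIIS, rose by 0.90 ± 0.14 and 0.86 ± 0.13, Pfdn6, a subunit of the chaperone prefoldin, by 0.83 ± 0.12, Ddrgk1 by 0.68 ± 0.09, Isoc2a by 0.67 ± 0.11 and Myl6 by 0.62 ± 0.10. The edgeR adjusted p was 0.0494 for Tceal5 and Isoc2a and 0.0465 for the other 6 genes. The count was 3003 at an unadjusted p under 0.05. DESeq2 called 721 genes, 386 rising and 335 falling. App differed by -0.31 ± 0.18 and Prnp by -0.43 ± 0.22. Without the library labelled 5xFAD;Ulk1OV replicate 3 they differed by -0.06 ± 0.11 and -0.12 ± 0.11.

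Camera called 12 of the 40 lists in 5xFAD;Ulk1OV against 5xFAD, 8 up and 4 down, each at an adjusted p of 0.841 with an estimated correlation. The respiratory chain list had the smallest p, with a median log2 fold change of 0.19: 2 of 38 members rose, 13 adjusted over the list alone (camera adjusted p = 1.21e-11). Cytosolic ribosome genes shifted up, with 6 of 43 rising adjusted over the list alone, Rps29 at 0.92 ± 0.18 and Rpl11 at 0.61 ± 0.13 (camera adjusted p = 5.82e-07; reads of ribosomal protein genes can be shared with their processed pseudogenes). The 13 protein genes of the mitochondrial genome went the other way: 7 fell adjusted over the list alone (camera adjusted p = 0.00051), with mt-Nd6, encoded on the opposite strand to its neighbour mt-Nd5 and so uncertain, at -0.64 ± 0.12. Fibroblast markers shifted up, with 7 of 14 rising adjusted over the list alone (camera adjusted p = 8.32e-06, and 5.29e-16 without the library labelled 5xFAD;Ulk1OV replicate 3, which lay with the 5xFAD libraries in this list), as did endothelium with 1 of 16 (camera adjusted p = 0.00228, and 0.108 without 5xFAD replicate 1) and antigen presentation with 1 of 18 (camera adjusted p = 0.000442, and 0.0796 without 5xFAD replicate 1). The blood list shifted up with 1 of 5 rising adjusted over the list alone (camera adjusted p = 0.0337). This call ended without 5xFAD replicate 1 (0.138), 5xFAD replicate 3 (0.265), 5xFAD;Ulk1OV replicate 1 (0.0902) or 5xFAD;Ulk1OV replicate 2 (0.0889).

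Stress and lipid lists were also called in 5xFAD;Ulk1OV against 5xFAD, but their calls ended without the library labelled 5xFAD;Ulk1OV replicate 3. Heat shock genes shifted up, with Hspb1, a small heat shock protein gene, at 1.43 ± 0.24 and rising adjusted over the list alone in 1 of 12 (camera adjusted p = 0.0142, and 0.349 without that library). Unfolded protein response genes shifted up with 1 of 16 rising adjusted over the list alone (camera adjusted p = 0.025, 0.525 without that library and 0.0569 without 5xFAD replicate 3). Cholesterol synthesis genes shifted down with 3 of 20 falling adjusted over the list alone (camera adjusted p = 0.0029, and 0.216 without that library). Dentate gyrus markers shifted down with 1 of 12 falling adjusted over the list alone (camera adjusted p = 0.00389, 0.0723 without that library and 0.157 without 5xFAD replicate 3). Synapse genes shifted down with 1 of 28 falling adjusted over the list alone (camera adjusted p = 0.0351, 0.349 without that library and 0.973 without 5xFAD replicate 1).

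The count of 8 genes in 5xFAD;Ulk1OV against 5xFAD changed with the libraries used. It was 0 without 5xFAD replicate 2, 5xFAD replicate 3, 5xFAD;Ulk1OV replicate 1 or 5xFAD;Ulk1OV replicate 2. It was 260 without 5xFAD replicate 1 (187 rising, 73 falling). Without the library labelled 5xFAD;Ulk1OV replicate 3 it was 12 (10 rising, 2 falling), 6 of the 8 among them (all but Tceal3 and Isoc2a). It was 0 with only the 6 libraries of the comparison. It was also 0 under a correction for GC content and transcript length, which also ended the call of the mitochondrial genome list (camera adjusted p = 0.127). With the correction the 8 genes had values of 0.48 to 0.82 (SE 0.08 to 0.14, edgeR adjusted p of 0.0787 to 0.103), against 0.62 to 0.94 (SE 0.09 to 0.14) without it. Each kept 70.6% to 91.6% of its value.

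The comparison of Ulk1OV with WT asked what Ulk1 overexpression changes on the wild-type background. Transcripts of 891 genes changed, 368 rising and 523 falling. With the possible batch, Ulk1 overexpression is not shown to be the source. Atp5k, a subunit of the mitochondrial ATP synthase, fell by 2.54 ± 0.33 on the log2 scale, from 65.5 ± 3 CPM in WT to 11.3 ± 3.98 in Ulk1OV (SD, n = 3). Egr1 and Junb, transcription factors that neurons switch on within minutes of firing, fell by 1.19 ± 0.16 and 1.33 ± 0.18, and Nuf2, a kinetochore gene, rose by 1.19 ± 0.16, from 3.81 ± 0.166 to 8.68 ± 0.697 CPM. The edgeR adjusted p of these 4 genes was 0.0106. DESeq2 called 1856 genes.

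**Figure D2:**
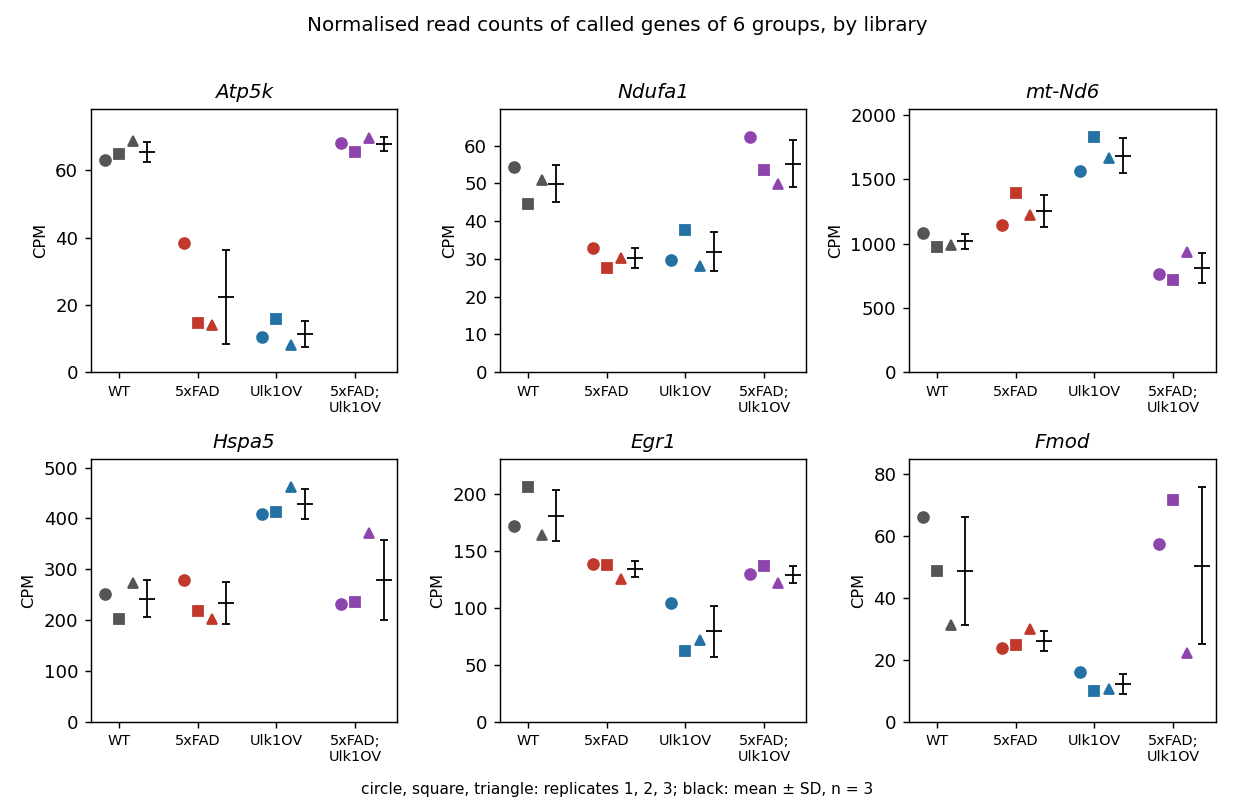
Normalised read counts (CPM) in each of the 12 libraries (circle, square and triangle for replicates 1, 2 and 3, by group, with mean ± SD in black, n = 3) for Atp5k, Ndufa1, mt-Nd6, Hspa5, Egr1 and Fmod. Atp5k lies between 63 and 69.7 CPM in the WT and 5xFAD;Ulk1OV libraries and between 7.9 and 38.3 in the 5xFAD and Ulk1OV libraries.

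Among genes named by the rule for the size of change, the largest falls in Ulk1OV against WT were those of Kcne4, a potassium channel subunit (-3.08 ± 0.80), the mitochondrial tRNA genes mt-Te (-2.92 ± 0.57) and mt-Tl2 (-2.80 ± 0.49), Asgr1 (-2.73 ± 0.65), Srp54a (-2.69 ± 0.58), the collagen gene Col3a1 and the mechanosensitive channel gene Piezo2 (-2.56 ± 0.57 each). The edgeR adjusted p of these genes was 0.0220 to 0.0437. Srp54a has near-identical copies and mitochondrial tRNAs are short and overlap their neighbours' transcripts, so those 3 values are uncertain. The largest rises among them, at an edgeR adjusted p of 0.0106 to 0.0458, were those of Tmem52 (1.48 ± 0.37), Tcp11 (1.46 ± 0.38), the cilium genes Spata17 (1.37 ± 0.35) and Cfap221 (1.36 ± 0.32), Inhba, an activin subunit (1.23 ± 0.27), the pseudogene Ak3l2-ps (1.22 ± 0.26, uncertain), Nuf2, and Scn9a, a sodium channel (1.11 ± 0.23).

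Camera called 16 of the 40 lists in Ulk1OV against WT, 6 up and 10 down. Among activity-dependent genes 10 of 24 fell and 1 rose, with 13 and 1 adjusted over the list alone (camera adjusted p = 3e-11, or adjusted p = 0.392 with an estimated correlation). Besides Egr1 and Junb these included Fos at -1.20 ± 0.20 and Egr4 at -1.43 ± 0.24 (edgeR adjusted p = 0.0196 and 0.0199). With the GC and length correction Egr4 stood at -0.88 ± 0.19 (edgeR adjusted p = 0.0355). Of 16 unfolded protein response genes 8 rose and 1 fell, with 11 and 3 adjusted over the list alone (camera adjusted p = 6.17e-06, or adjusted p = 0.464 with an estimated correlation). The lumenal chaperones Hspa5 and Hsp90b1 rose by 0.82 ± 0.18 and 0.76 ± 0.13 (edgeR adjusted p = 0.0292 and 0.0199), and Manf, a secreted stress protein gene, by 0.76 ± 0.11 (edgeR adjusted p = 0.0113). Of 12 heat shock genes 3 rose, and 6 adjusted over the list alone (camera adjusted p = 0.000321, or adjusted p = 0.472 with an estimated correlation), with Hspa8 up by 0.62 ± 0.11 (edgeR adjusted p = 0.0222). Of 20 cholesterol synthesis genes 4 fell, and 6 adjusted over the list alone (camera adjusted p = 1.22e-05, or adjusted p = 0.464 with an estimated correlation), among them Mvd, an enzyme of the mevalonate pathway, by 1.07 ± 0.17 (edgeR adjusted p = 0.0174).

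Mitochondrial lists moved apart in Ulk1OV against WT. Of the 13 protein genes of the mitochondrial genome 3 rose, and 6 adjusted over the list alone (camera adjusted p = 0.000163, or adjusted p = 0.464 with an estimated correlation), with mt-Nd6, which overlaps mt-Nd5 on the other strand and is uncertain, up by 0.73 ± 0.12 (edgeR adjusted p = 0.0169). Of 38 nuclear-encoded respiratory chain genes 5 fell, with 9 falling and 1 rising adjusted over the list alone (camera adjusted p = 0.0483, or adjusted p = 0.902 with an estimated correlation). The complex III subunit gene Uqcrfs1 fell by 0.50 ± 0.09 (edgeR adjusted p = 0.0249). The call of the respiratory chain list ended without Ulk1OV replicate 1 (camera adjusted p = 0.797), WT replicate 1 (0.223) or WT replicate 2 (0.0588), and under the correction for GC content and length (0.102).

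Several lists for cells outside the neuronal tissue shifted down in Ulk1OV against WT. The blood list was not called (camera adjusted p = 0.14), but was called down without Ulk1OV replicate 2 (0.0153), WT replicate 2 (0.0433) or WT replicate 3 (0.0335). Nor was the choroid plexus list, with a median of -0.39 over 16 genes but an upward test. It was called up without WT replicate 3 (camera adjusted p = 0.00037) and down without Ulk1OV replicate 1 (0.0235). Of 14 meningeal and perivascular fibroblast markers 10 fell, and 13 adjusted over the list alone (camera adjusted p = 6.51e-13, or adjusted p = 0.464 with an estimated correlation). Fmod, an extracellular matrix proteoglycan, fell by 2.00 ± 0.37, and Slc6a13, a GABA and taurine transporter of the meninges, by 1.90 ± 0.39 (edgeR adjusted p = 0.0222 and 0.0272). Of 16 endothelial markers 3 fell, and 5 adjusted over the list alone (camera adjusted p = 0.000772), among them Itm2a at -0.86 ± 0.21 (edgeR adjusted p = 0.0395). Of 11 mural cell markers 2 fell, Pdgfrb at -0.71 ± 0.15 and Vtn at -1.51 ± 0.32, and 3 adjusted over the list alone (camera adjusted p = 0.0111). Perivascular macrophage and leukocyte markers fell in 0 of 12, and in 5 adjusted over the list alone (camera adjusted p = 0.000806). The adjusted p with an estimated correlation was 0.464 for the endothelial and mural lists and 0.472 for the macrophage list.

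Immune lists fell as well in Ulk1OV against WT. Of 18 antigen presentation genes 4 fell, and 8 adjusted over the list alone (camera adjusted p = 1.61e-06, or adjusted p = 0.464 with an estimated correlation). H2-T23 and H2-D1, class I histocompatibility genes whose reads can be shared with their paralogs, fell by 0.98 ± 0.18 and 0.56 ± 0.12 (edgeR adjusted p = 0.0222 and 0.0287). Of 30 type I interferon response genes 2 fell, Ifi27 and Bst2, and 4 adjusted over the list alone (camera adjusted p = 0.000203, or adjusted p = 0.659 with an estimated correlation). Of 15 complement genes 1 fell, also adjusted over the list alone (camera adjusted p = 0.0393, or adjusted p = 0.464 with an estimated correlation). The complement call ended without Ulk1OV replicate 1 (0.0836) or WT replicate 1 (0.0559). Dentate gyrus markers shifted up with 1 of 12 rising adjusted over the list alone (camera adjusted p = 0.00214, or adjusted p = 0.578 with an estimated correlation, and 0.0588 by camera without WT replicate 2). Astrocyte markers shifted up with Gjb6, a gap junction gene, rising by 0.48 ± 0.12, and 2 of 17 adjusted over the list alone (camera adjusted p = 0.0393, or adjusted p = 0.786 with an estimated correlation). That call ended without Ulk1OV replicate 2 (0.166) or WT replicate 3 (0.16). Of 13 glucocorticoid response genes the metallothionein gene Mt1 rose by 0.68 ± 0.16, also adjusted over the list alone (camera adjusted p = 0.0111, or adjusted p = 0.659 with an estimated correlation). The glucocorticoid call ended without Ulk1OV replicate 2 (0.0546), WT replicate 1 (0.0646) or WT replicate 2 (0.065).

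The number of genes changed in Ulk1OV against WT was 0 without Ulk1OV replicate 3, WT replicate 1 or WT replicate 2, where the lowest edgeR adjusted p of the 56 named genes was 0.0943, 0.0584 and 0.0516. It was 493 without Ulk1OV replicate 1, 443 without WT replicate 3 and 1183 (449 rising, 734 falling) without the library labelled 5xFAD;Ulk1OV replicate 3; these removals ended the calls of 26, 23 and 0 of the 56 named genes, and removing Ulk1OV replicate 2 those of 14. Genes that rose had a median GC content of 45.6% and genes that fell 56.4%, against 50.4% over all genes tested. With the GC and length correction 439 genes were called, 227 rising and 212 falling, against 368 and 523 without it, and 337 were called in the same direction both ways. The correction ended the calls of Kcne4, Spata17 and Bst2 (edgeR adjusted p = 0.0516, 0.0609 and 0.0947), though Kcne4 went only from -3.08 ± 0.80 to -3.13 ± 0.79, Spata17 from 1.37 ± 0.35 to 1.28 ± 0.34 and Bst2 from -1 ± 0.26 to -0.80 ± 0.25. The unadjusted p of Kcne4 fell from 0.00183 to 0.00149, so its call ended through the adjustment over other genes.

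The comparison of 5xFAD;Ulk1OV with Ulk1OV asked what differs with the 5xFAD genotype when Ulk1 is overexpressed. Transcripts of 1051 genes changed, 632 rising and 419 falling. With the possible batch, the 5xFAD genotype is not shown to be the source. Cst7 rose by a log2 fold change of 4.08 ± 0.87, from 0.25 ± 0.267 to 4.39 ± 3.13 CPM (SD, n = 3; edgeR adjusted p = 0.0218), and Prnp by 0.83 ± 0.22 (edgeR adjusted p = 0.0457), while App, at 0.57 ± 0.18, did not pass (edgeR adjusted p = 0.0745). Without the library labelled 5xFAD;Ulk1OV replicate 3 both rose, Prnp by 1.14 ± 0.11 and App by 0.82 ± 0.11 (edgeR adjusted p = 0.00104 and 0.00452). Atp5k rose by 2.58 ± 0.33, to 67.8 ± 2.09 CPM (edgeR adjusted p = 0.0129), and mt-Nd6, which overlaps mt-Nd5 on the other strand, fell by 1.06 ± 0.12 (edgeR adjusted p = 0.00669). DESeq2 called 1992 genes. Of the genes changed in Ulk1OV against WT, 597 also changed here, each in the opposite direction. Both comparisons use the 3 Ulk1OV libraries, which adds shared genes of opposite sign without any effect. In 20 simulations without a group effect, run after the data were seen, edgeR called 0 genes in both comparisons. The 891 and 1051 genes of smallest p in those simulations shared 218 ± 12.8 (SD) in opposite directions. Independent lists of these sizes, sharing no library, would share 54.4. The covariance of the fold changes was -0.1736, against -0.0464 ± 0.00154 in the simulations. The simulations leave out real effects and perhaps noise shared across genes, so the excess over them is not a count of shared effects.

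Among genes named by the rule for the size of change, the largest rises in 5xFAD;Ulk1OV against Ulk1OV besides Cst7 and Atp5k were those of Kcne4 (3.20 ± 0.79), Asgr1 (2.84 ± 0.65), Slc6a12, a betaine and GABA transporter (2.56 ± 0.60), Hic1, a transcriptional repressor (2.43 ± 0.41), Col3a1 (2.37 ± 0.57) and Wnt6, a secreted Wnt ligand (2.34 ± 0.48). Their edgeR adjusted p was 0.0160 to 0.0339. The largest falls among them, at an edgeR adjusted p of 0.00669 to 0.0365, were those of Pabpc5 and Akr1c18, a progesterone-metabolising enzyme (-1.45 ± 0.37 and -1.45 ± 0.35), mt-Nd6, the kinase Nek11 (-1.05 ± 0.27), the zinc finger genes Zfp595 (-0.96 ± 0.19) and Zfp994 (-0.87 ± 0.17), mt-Nd5 (-0.92 ± 0.14) and the protocadherin Pcdhb5 (-0.90 ± 0.18). Zinc finger and protocadherin genes have close paralogs, and their counts are uncertain.

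Camera called 16 of the 40 lists in 5xFAD;Ulk1OV against Ulk1OV, 11 up and 5 down. Of 28 disease-associated microglia genes 6 rose, and 8 adjusted over the list alone (camera adjusted p = 3.57e-06, or adjusted p = 0.59 with an estimated correlation), among them the lipid receptor gene Trem2 at 0.78 ± 0.19, the lysosomal protease gene Ctsd at 0.59 ± 0.12 and Ccl6 at 0.94 ± 0.23 (edgeR adjusted p = 0.0330, 0.0195 and 0.0349). The GC and length correction ended the call of Trem2 (0.56 ± 0.18, edgeR adjusted p = 0.11). Of 24 activity-dependent genes 4 rose, with 11 rising and 1 falling adjusted over the list alone (camera adjusted p = 9.22e-06, or adjusted p = 0.59 with an estimated correlation), led by Egr4 at 1.36 ± 0.24 and Junb at 1.03 ± 0.18 (edgeR adjusted p = 0.0160). The correction ended these calls, at 0.74 ± 0.19 for Egr4 and 0.60 ± 0.18 for Junb (edgeR adjusted p = 0.0616 and 0.0945). Of the 13 mitochondrial genome genes 7 fell, and 8 adjusted over the list alone (camera adjusted p = 9.48e-08, or adjusted p = 0.59 with an estimated correlation). Of 20 cholesterol synthesis genes 3 rose, and 6 adjusted over the list alone (camera adjusted p = 0.0016, or adjusted p = 0.682 with an estimated correlation), with Mvd up by 0.94 ± 0.17 (edgeR adjusted p = 0.0160). Of 16 unfolded protein response genes 3 fell and 1 rose, 6 and 2 adjusted over the list alone (camera adjusted p = 0.0137, or adjusted p = 0.72 with an estimated correlation): Manf fell by 0.56 ± 0.11 and Hsp90b1 by 0.63 ± 0.13, and Atf4, a stress transcription factor, rose by 0.73 ± 0.11. That call ended without 5xFAD;Ulk1OV replicate 1 (0.0792), 5xFAD;Ulk1OV replicate 2 (0.0855) or Ulk1OV replicate 2 (0.0519).

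Respiratory chain and ribosome genes rose in 5xFAD;Ulk1OV against Ulk1OV in 5 of 38 and 3 of 43, and adjusted over the list alone in 11 and 4 (camera adjusted p = 0.00198 and 0.00552, or adjusted p = 0.72 and 0.757 with an estimated correlation). Both calls ended without Ulk1OV replicate 1 (0.415 and 0.991). Of 13 glucocorticoid response genes Mt1 fell by 0.63 ± 0.16, also adjusted over the list alone (camera adjusted p = 0.0306, or adjusted p = 0.72 with an estimated correlation). It was lost without 5xFAD;Ulk1OV replicate 1 (0.0683), 5xFAD;Ulk1OV replicate 2 (0.116) or Ulk1OV replicate 2 (0.132). Dentate gyrus markers shifted down with 2 of 12 falling adjusted over the list alone (camera adjusted p = 0.00794, or adjusted p = 0.72 with an estimated correlation), and to 0.0809 by camera without the library labelled 5xFAD;Ulk1OV replicate 3. Astrocyte markers shifted down with 2 of 17 falling adjusted over the list alone (camera adjusted p = 0.0492, or adjusted p = 0.72 with an estimated correlation). The astrocyte call ended without 5xFAD;Ulk1OV replicate 1 (0.244), 5xFAD;Ulk1OV replicate 2 (0.114), Ulk1OV replicate 2 (0.195) or Ulk1OV replicate 3 (0.0565).

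Several lists for coverings, vessels and immune cells shifted up in 5xFAD;Ulk1OV against Ulk1OV. The mural cell and blood lists were not called (camera adjusted p = 0.0706 and 0.0782). Both were called up without the library labelled 5xFAD;Ulk1OV replicate 3 (camera adjusted p = 0.0239 and 0.0423) and with only the 6 libraries (0.0422 and 0.0211), mural cells also without the filter on low counts (0.0218) and blood without Ulk1OV replicate 2 (0.0158). The choroid plexus list was not called either, with a median of -1.45 and 0 of 16 genes above 0 (camera adjusted p = 0.117). It was called down without Ulk1OV replicate 2 (camera adjusted p = 0.0212) or Ulk1OV replicate 3 (0.00217) and with only the 6 libraries (0.0211). Fibroblast markers rose in 9 of 14, and in 11 adjusted over the list alone (camera adjusted p = 2.76e-11, or adjusted p = 0.59 with an estimated correlation), with Fmod at 2.06 ± 0.37, Aldh1a2, a retinoic acid synthesis enzyme, at 2.21 ± 0.40 (edgeR adjusted p = 0.0160) and Slc6a13 at 2.09 ± 0.39 (edgeR adjusted p = 0.0164). Endothelial markers rose in 1 of 16, Itm2a at 0.95 ± 0.21, also adjusted over the list alone (camera adjusted p = 0.0212, or adjusted p = 0.72 with an estimated correlation). The endothelial call ended without 5xFAD;Ulk1OV replicate 2 (0.116), Ulk1OV replicate 2 (0.0706) or Ulk1OV replicate 3 (0.0565). Perivascular macrophage and leukocyte markers rose in 1 of 12, the B cell gene Cd79a at 3.27 ± 0.68, also adjusted over the list alone (camera adjusted p = 0.0104, or adjusted p = 0.72 with an estimated correlation). Antigen presentation genes rose in 3 of 18, and in 9 adjusted over the list alone (camera adjusted p = 1.96e-06, or adjusted p = 0.59 with an estimated correlation), with H2-T23 at 1.04 ± 0.18 and H2-D1 at 0.66 ± 0.12. Type I interferon genes rose in 1 of 30, Ifi27, and in 0 adjusted over the list alone by edgeR's test (camera adjusted p = 0.014, or adjusted p = 0.72 with an estimated correlation), and complement genes in 0 of 15 and in 3 adjusted over the list alone (camera adjusted p = 0.0212, or adjusted p = 0.59 with an estimated correlation). The interferon call ended without the library labelled 5xFAD;Ulk1OV replicate 3 (0.355) and the complement call without 5xFAD;Ulk1OV replicate 2 (0.0855).

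The number of genes changed in 5xFAD;Ulk1OV against Ulk1OV was 0 without 5xFAD;Ulk1OV replicate 1, 5xFAD;Ulk1OV replicate 2 or Ulk1OV replicate 3, where the lowest edgeR adjusted p of the 52 named genes was 0.0569, 0.0701 and 0.0542. It was 386 without Ulk1OV replicate 1, 1629 without Ulk1OV replicate 2 and 1579 (947 rising, 632 falling) without the library labelled 5xFAD;Ulk1OV replicate 3, and these removals ended the calls of 25, 5 and 1 of the 52 named genes. Genes that rose had a median GC content of 56.9% and genes that fell 44%, against 50.4% over all genes tested. With the GC and length correction 327 genes were called, 184 rising and 143 falling, 259 of them in the same direction as without it. Besides Trem2, Egr4 and Junb it ended 13 calls of genes named above (edgeR adjusted p of 0.0503 to 0.0966). Their SEs were 0.13 to 0.79 before and 0.11 to 0.79 after it. Prnp went from 0.83 to 0.84, Kcne4 from 3.20 to 3.28, Slc6a12 from 2.56 to 2.46, Akr1c18 from -1.45 to -1.31 and Nek11 from -1.05 to -0.98, and Col3a1 stayed at 2.37. These values moved by less than their SEs. The unadjusted p of Kcne4 and Col3a1 did not grow, so their calls ended through the adjustment over other genes. Wnt6 went from 2.34 to 1.86, Pabpc5 from -1.45 to -1.20, Zfp595 from -0.96 to -0.71, Zfp994 from -0.87 to -0.59, Mvd from 0.94 to 0.66, Hsp90b1 from -0.63 to -0.46 and Ifi27 from 0.63 to 0.55.

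The interaction tested whether the difference that goes with Ulk1 overexpression is itself different on the 5xFAD and the wild-type background. It called 2197 genes, 1171 with a positive and 1026 with a negative value, more than any of the 4 comparisons between groups. In Atp5k the value was 4.14 ± 0.45, with means of 22.3 CPM in 5xFAD, 67.8 in 5xFAD;Ulk1OV, 65.5 in WT and 11.3 in Ulk1OV. On the 5xFAD background alone Atp5k did not pass (log2 1.60 ± 0.31, edgeR adjusted p = 0.0597). The 5xFAD libraries held 38.3, 14.6 and 14.1 CPM, and without 5xFAD replicate 1 the interaction value was 4.80. Ndufa1 and Ndufa2 had values of 1.52 ± 0.18 and 1.51 ± 0.20, and mt-Nd6 of -1.36 ± 0.16, again uncertain because of its overlap with mt-Nd5. The edgeR adjusted p of these 4 genes was 0.00275. Ulk1 itself had a value of 0.12 ± 0.16 (edgeR adjusted p = 0.664), which turned to -0.24 under the GC and length correction, and App of -0.27 ± 0.26 (edgeR adjusted p = 0.53). Without the library labelled 5xFAD;Ulk1OV replicate 3 App had a value of 0 ± 0.15.

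Among genes named by the rule for the size of change, the highest interaction values beside Atp5k belonged to Tmem254c (6.32 ± 1.74, with near-identical copies and so uncertain), Kcne4 (4.39 ± 1.05), Asgr1 (4.24 ± 0.88) and Col3a1 (3.94 ± 0.78). The lowest among them belonged to Ada, adenosine deaminase (-2.11 ± 0.55), Akr1c18 (-2.04 ± 0.49), Spata17 (-1.93 ± 0.50), the neuropeptide gene Nts (-1.65 ± 0.39) and mt-Co3 (-1.60 ± 0.45). The edgeR adjusted p of these 9 genes was 0.00912 to 0.0353. The calls of Asgr1, Col3a1 and Nts held without any of the 12 libraries. That of Akr1c18 ended without 5xFAD;Ulk1OV replicate 2 (edgeR adjusted p = 0.0522), that of Kcne4 without 5xFAD;Ulk1OV replicate 2, Ulk1OV replicate 3 or WT replicate 1 (at most 0.0578). That of Tmem254c ended without 5xFAD replicate 2 or 3, 5xFAD;Ulk1OV replicate 1, Ulk1OV replicate 1 or 3, or WT replicate 2 (at most 0.164). That of Ada ended without 5xFAD replicate 3, 5xFAD;Ulk1OV replicate 2, Ulk1OV replicate 1, or WT replicate 1 or 2 (at most 0.0611), and that of Spata17 without 5xFAD replicate 2, 5xFAD;Ulk1OV replicate 1 or 2, Ulk1OV replicate 1, or WT replicate 1 or 2 (at most 0.0675). That of mt-Co3 ended without any library other than 5xFAD replicates 1 and 2, the library labelled 5xFAD;Ulk1OV replicate 3 and Ulk1OV replicate 2 (at most 0.0928). The correction for GC content and length ended the calls of Tmem254c, Nts and mt-Co3 (edgeR adjusted p = 0.0537, 0.052 and 0.13). With it Tmem254c stood at 6.30 ± 1.75, hardly changed, Nts at -1.25 ± 0.34 and mt-Co3 at -1.25 ± 0.46.

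Camera called 10 of the 40 lists in the interaction, 8 up and 2 down. Fibroblast markers had 10 of 14 members with a positive call, 13 adjusted over the list alone, with Slc6a13 at 3.13 ± 0.54 and Fmod at 2.95 ± 0.51 (camera adjusted p = 1.78e-12, or adjusted p = 0.552 with an estimated correlation). Antigen presentation genes had 9 of 18, and 14 positive and 1 negative adjusted over the list alone (camera adjusted p = 5.79e-07, or adjusted p = 0.552 with an estimated correlation), with H2-T23 at 1.70 ± 0.25. Respiratory chain genes had 10 of 38, and 15 adjusted over the list alone (camera adjusted p = 7.71e-07, or adjusted p = 0.815 with an estimated correlation). Activity-dependent genes had 11 positive and 1 negative of 24, 14 and 1 adjusted over the list alone, with Junb at 1.64 ± 0.26 and Egr4 at 1.92 ± 0.33 (camera adjusted p = 7.71e-07, or adjusted p = 0.552 with an estimated correlation). With the GC and length correction Junb stood at 0.96 ± 0.25 and Egr4 at 1.02 ± 0.27 (edgeR adjusted p = 0.0434 and 0.0424). Endothelial markers had 6 of 16, and 7 adjusted over the list alone, with Itm2a at 1.48 ± 0.30 (camera adjusted p = 0.000119, or adjusted p = 0.552 with an estimated correlation). The mitochondrial genome had 7 negative calls of 13, and 8 adjusted over the list alone (camera adjusted p = 1.2e-05, or adjusted p = 0.552 with an estimated correlation). Dentate gyrus markers had 3 of 12 negative, Pter, Rfx3 and Calb1, and 6 adjusted over the list alone (camera adjusted p = 0.00041, or adjusted p = 0.767 with an estimated correlation); the call of Calb1 ended without any library other than 5xFAD;Ulk1OV replicate 2 and Ulk1OV replicate 1 (edgeR adjusted p of at most 0.126) and under the GC and length correction (0.802), where it went from -0.54 ± 0.17 to -0.09 ± 0.17.

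The ribosome, perivascular macrophage and blood lists completed the interaction calls. Ribosome genes had 6 positive and 1 negative call of 43, the same numbers adjusted over the list alone, led by Rps29 at 1.55 ± 0.25 (camera adjusted p = 0.00866, or adjusted p = 0.929 with an estimated correlation). The ribosome call ended without Ulk1OV replicate 1 (0.416) and under the GC and length correction (0.164). Perivascular macrophage and leukocyte markers had 1 of 12, Cd79a at 4.10 ± 0.95 (at most 0.0538 as edgeR adjusted p without Ulk1OV replicate 3 or WT replicate 1, which ended its call), also adjusted over the list alone (camera adjusted p = 0.0169, or adjusted p = 0.868 with an estimated correlation). The list's call ended without 5xFAD replicate 1 (0.124) or WT replicate 1 (0.076). Blood genes had 1 of 5, the globin gene Hbb-bt at 3.77 ± 0.64, also adjusted over the list alone (camera adjusted p = 0.0435, or adjusted p = 0.891 with an estimated correlation). The call of the blood list ended without 5xFAD replicate 1 (0.124) or 3 (0.0893), 5xFAD;Ulk1OV replicate 1 (0.0587) or 2 (0.0566), Ulk1OV replicate 1 (0.0977) or 3 (0.0664), or WT replicate 1 (0.111).

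**Figure D3:**
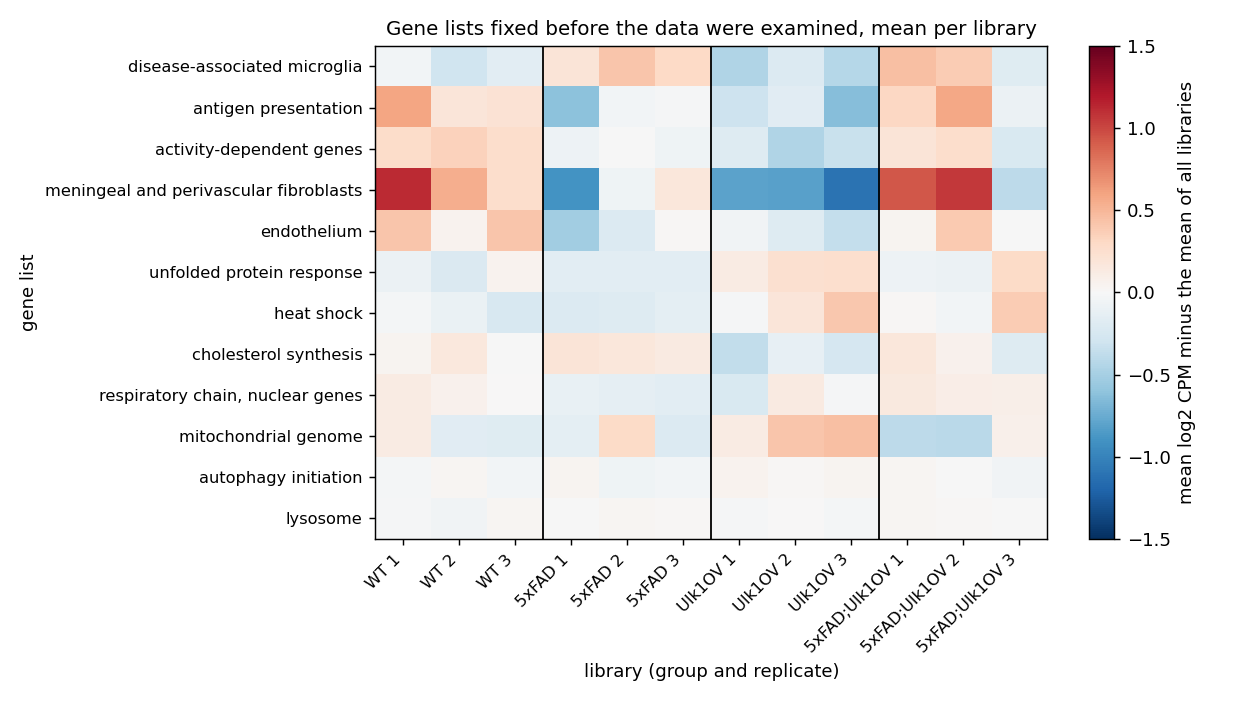
Mean log2 deviation of each list's genes from their mean over the 12 libraries (colour, log2 units), for 12 gene lists (rows) in 12 libraries (columns, by group). Meningeal and perivascular fibroblast markers average 0.64 in WT, 0.53 in 5xFAD;Ulk1OV, -0.27 in 5xFAD and -0.91 in Ulk1OV. They lie at 0.933 and 1.06 in 5xFAD;Ulk1OV replicates 1 and 2 and at -0.398 in the library labelled 5xFAD;Ulk1OV replicate 3, and at -0.901 in 5xFAD replicate 1 against -0.062 and 0.166 in the other 5xFAD libraries.

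The interaction count was 2539 (1455 positive, 1084 negative) without the library labelled 5xFAD;Ulk1OV replicate 3. It was 974 without Ulk1OV replicate 3, 1008 without 5xFAD;Ulk1OV replicate 2, 1048 without WT replicate 1, 1145 without 5xFAD;Ulk1OV replicate 1, 1246 without 5xFAD replicate 3, 1255 without WT replicate 2 and 1361 without 5xFAD replicate 2. Genes with a positive call had a median GC content of 56.5% and genes with a negative call 44.3%, against 50.4% over all genes tested. With the GC and length correction 901 genes were called, 431 positive and 470 negative, 642 of them in the same direction as without it.

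**Figure D4:**
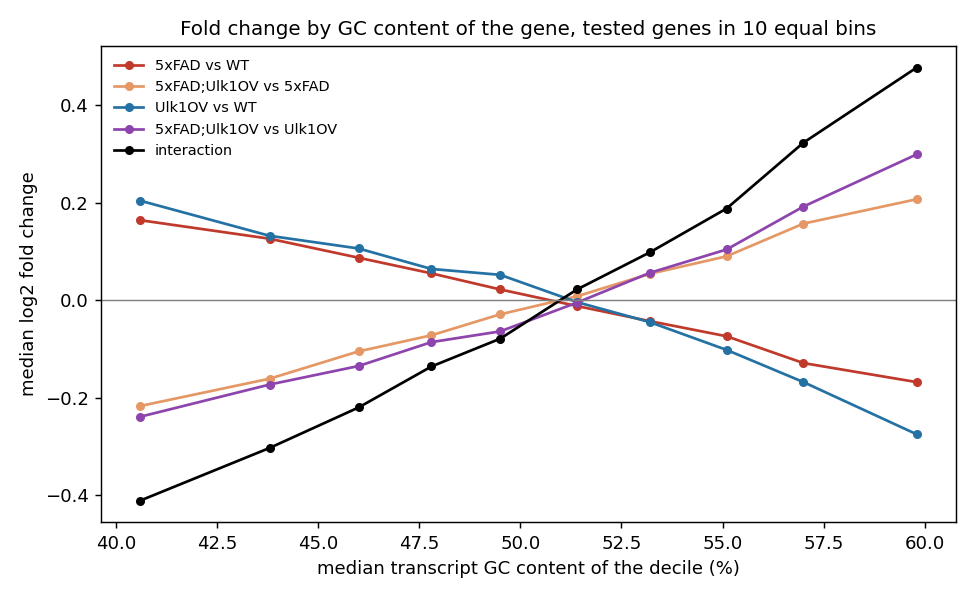
Median log2 fold change of tested genes (y axis, log2 units) in 10 equal bins of transcript GC content (x axis, percent), with 1 line for each comparison and the interaction. Across genes the Spearman correlation of fold change with GC content is -0.41 in 5xFAD against WT, 0.45 in 5xFAD;Ulk1OV against 5xFAD, -0.39 in Ulk1OV against WT, 0.46 in 5xFAD;Ulk1OV against Ulk1OV and 0.51 in the interaction.

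Ulk1 acts at the start of autophagy, so the autophagy lists were looked at in every comparison. With all 12 libraries and without the GC and length correction camera called none of them. The lowest camera adjusted p over the 4 comparisons and the interaction was 0.377 for 18 autophagy initiation genes, 0.405 for 23 autophagosome formation genes, 0.413 for 16 mitophagy genes, 0.347 for 34 lysosome genes and 0.267 for 21 genes of mTOR and AMPK signalling. With the correction, chosen after the data were seen, camera called mitophagy down in 5xFAD;Ulk1OV against 5xFAD (adjusted p = 0.0176). It then also called lysosome up in 5xFAD against WT (adjusted p = 0.0363) and autophagy initiation down in 5xFAD;Ulk1OV against Ulk1OV (adjusted p = 0.0447). Single genes were called by edgeR without the correction. In Ulk1OV against WT 1 initiation gene rose, 3 autophagosome formation genes rose and 2 fell, and 2 mTOR and AMPK genes fell. In 5xFAD;Ulk1OV against Ulk1OV 2 initiation genes fell, 2 autophagosome formation genes rose and 1 fell, and 2 lysosome and 3 mTOR and AMPK genes rose. The interaction had 1 negative call among initiation genes, 3 positive and 4 negative among autophagosome formation, 2 and 3 among mitophagy, and 3 and 2 among lysosome and among mTOR and AMPK genes. The 8 genes called in 5xFAD;Ulk1OV against 5xFAD are in none of these lists.

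Other lists not called in any comparison, with all 12 libraries and without the GC and length correction, had a lowest camera adjusted p of 0.119 (homeostatic microglia), 0.0521 (reactive astrocytes), 0.197 (GABAergic interneurons), 0.058 (CA1 and CA3), 0.522 (neurogenesis), 0.25 (oligodendrocytes and myelin), 0.656 (oligodendrocyte precursors), 0.25 (amyloid precursor processing), 0.504 (proteasome), 0.205 (circadian clock) and 0.168 (nuclear-retained RNA). Markers of neighbouring brain regions were not called either, with a lowest camera adjusted p of 0.398 for thalamus and habenula, 0.347 for striatum and 0.322 for neocortex. Of these 19 lists, the autophagy lists included, camera called 12 under another setting or without 1 library.

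Oligodendrocyte and myelin genes were called up in 5xFAD against WT without 5xFAD replicate 1 (camera adjusted p = 9.34e-08) or WT replicate 3 (0.000103). They were called down in 5xFAD;Ulk1OV against 5xFAD without 5xFAD replicate 1 (camera adjusted p = 5.6e-07) or the library labelled 5xFAD;Ulk1OV replicate 3 (0.021), and down in the interaction without 5xFAD replicate 1 (0.0484). CA1 and CA3 markers were called down in Ulk1OV against WT without Ulk1OV replicate 1 (camera adjusted p = 0.0142) or WT replicate 3 (0.0195), without the filter on low counts (0.0184) and with only the 6 libraries (0.0295). They were called up in 5xFAD;Ulk1OV against Ulk1OV without Ulk1OV replicate 1 (camera adjusted p = 0.0209) or 5xFAD;Ulk1OV replicate 2 (0.0459), without the filter (0.0328) and with only the 6 libraries (0.0211). Reactive astrocyte genes were called up in 5xFAD;Ulk1OV against Ulk1OV without the library labelled 5xFAD;Ulk1OV replicate 3 (camera adjusted p = 0.0179), without the filter (0.0129), with only the 6 libraries (0.0416) and with the GC and length correction (0.0128). Homeostatic microglia genes were called up in 5xFAD against WT without 5xFAD replicate 3 (camera adjusted p = 0.00572) or WT replicate 1 (0.0108). They were called down in 5xFAD;Ulk1OV against 5xFAD without 5xFAD replicate 3 (camera adjusted p = 0.00612) and with the correction (0.0407). Interneuron genes were called down in 5xFAD against WT without 5xFAD replicate 3 (camera adjusted p = 0.00698) and in 5xFAD;Ulk1OV against Ulk1OV with the correction (0.0472). Amyloid precursor processing was called down in 5xFAD;Ulk1OV against 5xFAD with the correction (camera adjusted p = 0.0407). In Ulk1OV against WT the proteasome was called up without Ulk1OV replicate 1 (camera adjusted p = 0.0164) and the circadian clock down without WT replicate 1 (0.0388). Nuclear-retained RNA was called down in 5xFAD;Ulk1OV against Ulk1OV without the library labelled 5xFAD;Ulk1OV replicate 3 (camera adjusted p = 0.00953). Lists called in 1 comparison could also be gained in another. Of the lists called elsewhere but not in the comparison itself, camera called 7 of 11 in 5xFAD against WT under another setting or without 1 library. These numbers were 3 of 9 in 5xFAD;Ulk1OV against 5xFAD, 5 of 5 in Ulk1OV against WT, 4 of 5 in 5xFAD;Ulk1OV against Ulk1OV and 6 of 11 in the interaction. Among them, the interaction called type I interferon genes up with the GC and length correction (camera adjusted p = 0.00235) and glucocorticoid response genes down with it (0.0105). In each called list the median, the mean and the test had the same sign, while among lists not called they differed in sign in 3 to 8 lists per comparison.

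Whether genes that differ between 5xFAD and WT move back with Ulk1 overexpression could not be read from called genes, since edgeR called 0 genes in 5xFAD against WT (2139 at an unadjusted p under 0.05, 136 by DESeq2). Over all 17227 genes the covariance of the log2 fold changes of 5xFAD against WT and of 5xFAD;Ulk1OV against 5xFAD was -0.1089, and 80.2% of genes had opposite signs. Both comparisons use the 5xFAD libraries. In 20 simulations without any effect of Ulk1 overexpression on the 5xFAD background the covariance was -0.0637 ± 0.0043 (SD) and 60.3% of genes had opposite signs. The simulations kept the observed difference of 5xFAD from WT. Their SD may leave out noise shared across genes. On the simulations' mean log CPM scale the observed covariance was -0.1237 (jackknife SE within groups 0.012, rough at 3 libraries per group). The difference of -0.06 from the simulations has no SE. With 1 of the 3 5xFAD libraries in one comparison and the others in the other, done after the data were seen, no library was shared. Over the 6 such splits, not independent of each other, the covariance was -0.0651 to -0.0403, and 58.1% to 67% of genes had opposite signs. The comparison of 5xFAD;Ulk1OV with Ulk1OV shares no library with that of 5xFAD and WT, and across genes their fold changes had a Spearman correlation of -0.45, with genes not independent replicates. Fold changes followed GC content in opposite directions in 5xFAD against WT and 5xFAD;Ulk1OV against 5xFAD (Spearman -0.41 and 0.45). Some lists, such as the respiratory chain, were called in opposite directions there. The disease-associated microglia list, called up in the former, was not called in the latter (camera adjusted p = 0.755, or 0.237 and upward without the library labelled 5xFAD;Ulk1OV replicate 3).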

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

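The tests of the library labelled 5xFAD;Ulk1OV replicate 3, of the GC trend, of an unrecorded batch and of Thy1 were chosen after their results were seen. The splits, the meningeal covariate and the neighbours of Prnp were planned. Of 109 named genes, 73 were called by the interaction term, the difference that goes with the Ulk1OV label on the 5xFAD background minus that on the wild-type background (edgeR adjusted p from 0.00275 to 0.0485). Ulk1 overexpression is not shown to be its source. They are given by their log2 difference, 51 positive and 22 negative. The 109 genes are those always named, those named for the size or smallest p of their change, the first 2 of each called list, and Lamr1-ps1 and Cst7, chosen after their values were seen. The limit of 2 was set after the calls had been counted. Some of the genes were named because the interaction called them, so the share is no rate for all genes. The GC and length correction ended 20 of the 73 calls (edgeR adjusted p of 0.052 to 0.802), with SEs of 0.15 to 1.74 before and 0.15 to 1.75 after it. Of these, Tmem254c went from 6.32 to 6.3, Piezo2 from 2.53 to 2.61, Dusp1 from 1.21 to 1.07, Nek11 from -1.26 to -1.14 and Inhba from -1.34 to -1.18, each by less than its SE. The unadjusted p of Piezo2 fell from 0.00595 to 0.00422, so its call ended through the adjustment over other genes. The rest of the 20 kept 17.3% to 77.9% of their value: Cldn5 went to 1.46, Hspb1 to 0.92, Esam to 0.88, Pdgfrb to 0.65, H2-D1 to 0.54, Atf4 to 0.46, C1qa to 0.22, Ctsd to 0.34, Calb1 to -0.09, Hsp90b1 to -0.33, Zfp994 to -0.56, Zfp595 to -0.71, mt-Nd5 to -0.66, mt-Co3 to -1.25 and Nts to -1.25. Among the calls made both ways, it moved Egr4 from 1.92 to 1.02, Junb from 1.64 to 0.96, Mvd from 1.39 to 0.92 and Ddrgk1 from 1.01 to 0.67.

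Among genes of the coverings, vessels, blood and immune cells the log2 difference was 4.1 for Cd79a, 3.94 for Col3a1, 3.78 for Slc6a12, 3.77 for Hbb-bt, 3.65 for Wnt6, 3.61 for H2-Eb1, 3.55 for Hic1, 3.13 for Slc6a13, 3.02 for Aldh1a2, 2.95 for Fmod, 2.85 for Col1a2, 2.5 for Vtn, 2.18 for Igfbp2, 1.98 for Cldn5, 1.7 for H2-T23, 1.48 for Itm2a, 1.35 for Tek, 1.14 for Esam, 1.11 for Ifi27, 0.88 for Pdgfrb, 0.76 for H2-D1, 0.7 for C1qa and 0.55 for Ctsd. Among mitochondrial, ribosomal and stress genes it was 4.14 for Atp5k, 3.85 for mt-Tl2, 2.76 for mt-Te, 1.55 for Rps29, 1.52 for Ndufa1, 1.51 for Ndufa2, 1.51 for Hspb1, 1.32 for Rplp1, 0.84 for Rpl11, 0.76 for Uqcrfs1, 0.73 for Atf4, -0.6 for Hsp90b1, -0.65 for Hspa8, -0.76 for Hsp90aa1, -1.03 for Mt1, -1.13 for mt-Nd5, -1.36 for mt-Nd6 and -1.6 for mt-Co3. Among activity-dependent and neuronal genes it was 1.92 for Egr4, 1.64 for Junb, 1.62 for Btg2, 1.21 for Dusp1, 1.13 for Egr1, -0.54 for Calb1, -0.75 for Rfx3, -0.81 for Pter, -1.34 for Inhba, -1.36 for Pcdhb5 and -1.65 for Nts. Among the others it was 6.32 for Tmem254c, 4.39 for Kcne4, 4.24 for Asgr1, 2.98 for Srp54a, 2.53 for Piezo2, 1.59 for Tceal5, 1.43 for Pfdn6, 1.39 for Mvd, 1.36 for Tceal3, 1.02 for Isoc2a, 1.01 for Ddrgk1, 1 for Myl6, -0.74 for Utp15, -1.03 for Zfp994, -1.12 for Zfp595, -1.22 for Ak3l2-ps, -1.24 for Nuf2, -1.26 for Nek11, -1.93 for Spata17, -2.04 for Akr1c18 and -2.11 for Ada.

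The library labelled 5xFAD;Ulk1OV replicate 3 lacked the reads that mark the other 5xFAD libraries. Lower depth was excluded, since its total was 98.8% of the mean of the others, and so was lowering by Ulk1 overexpression, since the other 5xFAD;Ulk1OV libraries held 0.911 of the 5xFAD mean of Prnp. A swap within the series was excluded, since the highest Lamr1-ps1 count in a library without the 5xFAD label was 0. In 4 of 4 genes (App, Prnp, Lamr1-ps1 and Cst7) it lay below every other library with the label and at most 1.5 times the highest without it, so a candidate explanation is a sample without the 5xFAD transgenes under a wrong label. Genes picked because they showed the pattern were part of that test, and the source of the sample stays open.

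The interaction called genes of high GC content in 1 direction and of low GC content in the other. The correction took the Spearman correlation of the interaction values with GC content from 0.51 to 0. After it 29.2% of the calls were also made in the same direction. It moved the median log2 difference of the calls from 0.73 to 0.47 and its SE from 0.18 to 0.16. By a bound set after the data were seen, a trend of the kind it removes was not the whole cause. It may still account for part of the calls. Bias that a trend over whole genes does not capture was not tested and is not excluded. With the fibroblast list as a covariate 0% of the calls were made again, which met the bound written beforehand for meningeal tissue as the cause, but the median log2 difference went only from 0.73 to 0.64 while the SE rose from 0.18 to 0.28, and 66.8% of the covariate's variance lay between groups; that explanation was set to undecided after this was seen. WT and 5xFAD;Ulk1OV libraries were separated completely from 5xFAD and Ulk1OV libraries in 855 genes, against 37 and 20 under the other pairings of groups and 37.3 by chance (0.216% of genes). An unrecorded batch along that pairing cannot be told apart from an interaction of the genotypes, because both are the same contrast.

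Prnp and App stood higher in libraries with the 5xFAD label, leaving out the library labelled 5xFAD;Ulk1OV replicate 3, by 2.25-fold and 1.78-fold, and Thy1, whose promoter drives the published 5xFAD transgenes, did not. The upper 95% limit of the Thy1 log2 difference between 5xFAD and WT was 0.11, which excludes an equal rise. A transgene with little Thy1 sequence is not excluded. A transgene that carries Prnp sequence is a candidate explanation: the 3 other tested genes within 300 kb of Prnp had a median absolute log2 difference of 0.11 (5330413P13Rik 0.07, Rassf2 -0.11, Slc23a2 -0.13), so the difference did not extend to its neighbours. Whether published transgenes carry Prnp sequence was not tested. These counts do not identify the construct behind the 5xFAD label. A change of the mouse Prnp gene itself stays open, since gene counts do not separate it from transgene reads.

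Other splits of the same libraries were fitted for each count. With 10 splits of 6 libraries no share under 0.05 can be had. The real split and the highest other split called 0 and 10 genes in 5xFAD against WT by edgeR (2139 at an unadjusted p under 0.05 and 136 by DESeq2 in the real split; 10 of 10 splits called as many), 8 and 1 in 5xFAD;Ulk1OV against 5xFAD (1 split as many, the real one), 891 and 0 in Ulk1OV against WT (1) and 1051 and 0 in 5xFAD;Ulk1OV against Ulk1OV (1). Lists were called in numbers no larger than in other splits: 10 and 17 in 5xFAD against WT (6 of 10 splits as many), 12 and 18 in 5xFAD;Ulk1OV against 5xFAD (7), 16 and 18 in Ulk1OV against WT (3) and 16 and 19 in 5xFAD;Ulk1OV against Ulk1OV (4). For the interaction 100 of 200 splits were drawn. Only the real split, which was always included, reached 2197 genes (1 of 100, the smallest share possible), with 1982 in the highest other. That share is under 0.05, but the splits not drawn were not fitted, so chance is made less likely for the gene count and not excluded. For lists, 70 of 100 splits called at least as many as the real 10, with 21 at most, so chance was not excluded for the list count. The split with 1982 genes exchanged the library labelled 5xFAD;Ulk1OV replicate 3 for 5xFAD replicate 1.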

How the results depend on the processing

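Chosen after the data were seen were the correction for GC content and length, the values of 5xFAD against WT and Ulk1OV against WT without the library labelled 5xFAD;Ulk1OV replicate 3, and the values of single genes with 6 libraries or 1 left out; the others were planned. Camera with an estimated correlation called 0 lists in each of the 4 comparisons and the interaction; no other setting, left-out libraries included, moved a count of lists by over 1.5 times. In the order 5xFAD against WT, 5xFAD;Ulk1OV against 5xFAD, Ulk1OV against WT and 5xFAD;Ulk1OV against Ulk1OV, the genes called were 551, 901, 2079 and 2097 without a filter on low counts, and 136, 721, 1856 and 1992 by DESeq2; the interaction count stayed within 1.5 times under both. The covariance of 5xFAD against WT with 5xFAD;Ulk1OV against 5xFAD went from -0.1089 to -0.7003 without the filter, -0.4817 by DESeq2 and -0.0929 under the GC and length correction. With DESeq2's size factors 18 genes were called in 5xFAD;Ulk1OV against 5xFAD. With only the 6 libraries of a comparison, edgeR called 2 genes in 5xFAD against WT, 0 in 5xFAD;Ulk1OV against 5xFAD and 430 in 5xFAD;Ulk1OV against Ulk1OV. Under the GC and length correction 0 genes were called in 5xFAD;Ulk1OV against 5xFAD, 439 in Ulk1OV against WT, 327 in 5xFAD;Ulk1OV against Ulk1OV and 901 in the interaction. It turned the sign of Ulk1 in 5xFAD against WT (0.06), 5xFAD;Ulk1OV against Ulk1OV (-0.18) and the interaction (-0.24), and of Thy1 in 5xFAD against WT (0.07) and 5xFAD;Ulk1OV against 5xFAD (-0.15). Beside each 0 for 5xFAD;Ulk1OV against 5xFAD stand 3003 genes at an unadjusted p under 0.05 with all libraries and 721 by DESeq2. For these results the cause was not tested, except that testing 6 libraries leaves fewer samples.

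With the replicate block edgeR called 0 genes in 5xFAD;Ulk1OV against 5xFAD, and the block moved no other count of genes or lists by over 1.5 times. With it camera called the CA1 and CA3 list in Ulk1OV against WT (adjusted p = 0.0434) and 5xFAD;Ulk1OV against Ulk1OV (0.0491). The numbers did not pair the libraries: 4 of 18 same-numbered pairs had a correlation over 0.1 (from -0.18 to 0.22), and 5 of 12 libraries correlated best with their own number.

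With each library left out in turn, the genes called ranged from 0 to 39 in 5xFAD against WT (highest without 5xFAD replicate 1), 0 to 260 in 5xFAD;Ulk1OV against 5xFAD (highest without 5xFAD replicate 1), 0 to 1183 in Ulk1OV against WT (highest without the library labelled 5xFAD;Ulk1OV replicate 3, 0 without Ulk1OV replicate 3, WT replicate 1 or WT replicate 2), 0 to 1629 in 5xFAD;Ulk1OV against Ulk1OV (0 without 5xFAD;Ulk1OV replicate 1 or 2 or Ulk1OV replicate 3) and 974 to 2596 in the interaction (lowest without Ulk1OV replicate 3), and the covariance from -0.1659 to -0.1042. Log2 values that changed sign ranged, in 5xFAD against WT, from -0.23 to 0.01 for Ulk1, -0.13 to 0.01 for Thy1, -5.15 to 0.68 for Kcne2 (highest without WT replicate 3) and -0.95 to 0.15 for Hba-a2 (highest without WT replicate 1). In 5xFAD;Ulk1OV against 5xFAD they ranged from -0.04 to 0.1 for Thy1 and -0.68 to 0.19 for Cst7, and in Ulk1OV against WT from -0.11 to 0.01 for App, -0.02 to 0.08 for Thy1 and -0.95 to 1.1 for Cst7. Ulk1 in 5xFAD;Ulk1OV against Ulk1OV ranged from -0.02 to 0.12, and in the interaction Alas2 from -0.24 to 0.89 and Cst7 from -1.43 to 0.64. Depth limits genes with few counts: Cst7 had 0 to 9 counts in the WT and Ulk1OV libraries, where counting error is large.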

Other observations

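The genes below were chosen after their values were seen. Ptgds, which encodes a prostaglandin D synthase abundant in the meninges and choroid plexus, stood at 3259 and 3197 CPM in 5xFAD;Ulk1OV replicates 1 and 2 and at 1276 in the library labelled 5xFAD;Ulk1OV replicate 3. It stood at 2793, 1656 and 1314 CPM in WT, at 703.8, 1031 and 1172 in 5xFAD and at 617.8, 641.5 and 536.7 in Ulk1OV. Ttr stood at 5949 CPM in WT replicate 3 and 3994 in Ulk1OV replicate 1, and between 5.088 and 285 in the other 10 libraries. The pseudogene Rps26-ps1, whose reads can be shared with Rps26, stood at 44.15 and 44.07 CPM in 5xFAD;Ulk1OV replicates 1 and 2, at 1.726 in the library labelled 5xFAD;Ulk1OV replicate 3, and between 0.5448 and 6.892 in the other 9.

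The first principal component of the log CPM values held 24.3% of the variance, and its gene loadings had a Spearman correlation of -0.46 with GC content, across genes, which are not independent replicates. On it 5xFAD;Ulk1OV replicates 1 and 2 lay at -29.1 and -30.5 and the library labelled 5xFAD;Ulk1OV replicate 3 at 6.8. WT libraries lay at -29.1, -22.1 and -4.8, 5xFAD libraries at -9, 10.3 and 6.3 and Ulk1OV libraries at 35.8, 24.1 and 41.3.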
